A study of Mus musculus with 12 samples.

How the data were processed

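RNA was sequenced from mouse bone marrow-derived macrophages, which are marrow cells grown for 7 days in medium with L929 cell supernatant, a source of macrophage growth factor. Per the labels, the donors were male C57BL/6 mice without a working Apoe gene. The Dicer KO mice carried LysM-Cre, a Cre recombinase placed in the Lyz2 locus and active in myeloid cells, and floxed copies of Dicer1. Dicer1 encodes the enzyme that cuts microRNA precursors into mature microRNAs. Littermate controls are titled as carrying LysM-Cre with unfloxed Dicer1, while another field of the labels calls them wildtype. The names of the control files mark the LysM locus as wildtype, and those of the Dicer KO files mark it as carrying Cre. All cultures received diluted ethanol overnight, per the labels' protocols, and then phosphate-buffered saline (vehicle) or lipopolysaccharide (LPS), a bacterial cell wall component that activates TLR4, for 6 h. The labels give the LPS concentration as 100 ng/ul. There were 12 libraries in 4 groups of 3. The labels do not say whether the replicates of a group came from separate mice, so the p-values measure the spread between these samples, which is technical in part or in full if they shared mice.

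The library kit was a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name STAR 2.5, DESeq2 without a version, and the genome builds mm10 and GRCm38.p5. Each file deposited by the authors holds whole-number read counts per Ensembl gene for 1 library, followed by counts of reads assigned to no gene. The counting program, its strand setting and the annotation release are not given in the sources used here. Per the file contents, 45.8 to 46.8% of reads fell on no annotated gene, 0.630 to 0.770% were ambiguous, 9.85 to 11.6% did not align to a unique place, and 41.7 to 43.3% were assigned to genes. All 13 protein-coding genes of the mitochondrial genome are listed at 0 in all 12 libraries, so that list was not tested.

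Of the 46078 gene identifiers, 45143 matched GENCODE mouse release M21, which supplied the symbols and the GRCm38 coordinates. The unmatched identifiers held 0.141% of the counts. Because the strand setting is not given, a named gene whose exons overlap exons on the opposite strand is reported with the overlapping share. Genes with close paralogs can share or lose reads between copies, and this is stated where such genes are named.

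Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr were kept, 13837 in all, library sizes were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with robust dispersion was fitted to all 12 libraries with 1 mean per group. The biological coefficient of variation was 6.30%. There were 5 comparisons, which were Dicer KO against control in vehicle and in LPS, LPS against vehicle in each genotype, and the difference of the LPS responses between genotypes (the interaction). Benjamini-Hochberg adjustment was made within each comparison, and a gene was called at an adjusted p under 0.05. All tests were two-sided. Levels are CPM, the read count scaled to the TMM-adjusted library size, given as mean and SD over n = 3 libraries, and errors of log2 fold changes are standard errors (SE) of the model. TMM sets the typical gene at no change, so every fold change is relative to the bulk of the genes and says nothing about total RNA per cell.

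The 35 gene lists, the comparisons, the tests and the naming rule were written before the data were examined. Lists were tested with camera (limma 3.58.1), which compares the members of a list with all other genes, at a preset correlation between genes of 0.01. The p-values were adjusted over all 155 list tests, and the same tests were repeated with a correlation estimated for each list. Lists needed at least 3 measured genes. This left out the mitochondrially encoded genes with 0 of 13 measured, the erythroid markers with 0 of 10, the T and NK lymphocyte markers with 2 of 12, and the stromal markers with 1 of 12. For each list, the members called were counted with p adjusted over all genes and with p adjusted over the list alone. Some lists share members, so their results are not independent. Socs1, Tab2 and Irak1 are in both the TLR4 list and the macrophage microRNA targets. Abca1 and Abcg1 are in both the efflux list and those targets, and Ldha, Pgk1 and Pfkfb3 in both the hypoxia and glycolysis lists.

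Named genes followed a rule. In each pairwise comparison it takes the 10 largest rises and the 10 largest falls among called genes whose higher group has a mean of at least 5 CPM and whose groups do not overlap, leaving out predicted genes. The interaction names the 10 largest in each direction without the overlap condition. Up to 4 members of each list with the smallest adjusted p are named as well, and 12 genes are always reported (Dicer1, Apoe, Lyz2, Lcor, Tnf, Il6, Il1b, Nos2, Arg1, Cpt1a, Hadhb and Abca1). List members that moved against the rest of their list, and genes named beside a list without being among its smallest adjusted p, were chosen after their values were seen. Some genes that the rule takes are not reported here. Where a group had 0 counts, a fold is given as a bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with a 95% counting interval. Floors and intervals cover counting error only.

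MicroRNA target sites were tested in the annotated 3′ untranslated regions of 11660 tested genes for 28 microRNA families, 22 common in macrophages and 6 for comparison. For each family a linear model compared the log2 fold changes of genes with and without a site that matches the seed, with adjustment for the length and GC content of the region, and the difference was ranked among up to 200 shuffled 7-base sites of like composition. Site searches used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6.

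The model was tested on simulated data. Counts for 13837 genes were made at the depth and spread of these libraries with known changes of 1.5-fold, 2-fold and 4-fold. Of these genes 13445 passed the filter on the simulated counts and were tested. In the vehicle genotype comparison 73.1, 94.0 and 98.5% of these genes were called, with 10 false calls. For the interaction the shares were 58.2, 77.6 and 93.9%, with 6 false calls. The changed genes numbered 67, 67 and 66, none at the lowest levels. Genes were drawn independently, with no LPS effect and no library standing apart. The real comparisons called far more genes, so these shares need not carry over to them.

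Alternatives fixed beforehand were DESeq2 1.42.0 and limma voom in place of edgeR, relative log expression scaling, no filter and a stricter filter on low counts, each library left out in turn, the replicate number as a block, an estimated correlation for the lists, and other site definitions. Added after seeing the data were library totals without scaling factors, and leaving out control vehicle replicate 3 together with Dicer KO vehicle replicate 2. Figures were drawn with matplotlib 3.10.9. Reads on no gene were used only to describe the libraries, and their sequence was not analysed here.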

Results

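Messenger RNA was measured in 12 libraries of bone marrow-derived macrophages, 3 each of control with vehicle, control with LPS, Dicer KO with vehicle and Dicer KO with LPS. Counts assigned to genes were 18552400 to 18886948 per library in control vehicle, 16172600 to 18084877 in Dicer KO vehicle, 17136578 to 17941058 in control LPS and 18671876 to 18785476 in Dicer KO LPS. Between 17089 and 18512 genes had a count, and the 20 most abundant genes held 11.3 to 14.2% of the counts. The first principal component, with 88.6% of the variance, separated LPS from vehicle, and the second, with 7.80%, separated the genotypes. Among replicates, control vehicle replicate 3 and Dicer KO vehicle replicate 2 stood apart from the others of their groups. The count spread of a replicate pair, as chi-square per degree of freedom, was 9.93 and 14.3 for the pairs with control vehicle replicate 3 against 2.55 for the other pair of that group. For Dicer KO vehicle replicate 2 it was 8.42 and 11.9 against 2.30.

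**Figure D1:**
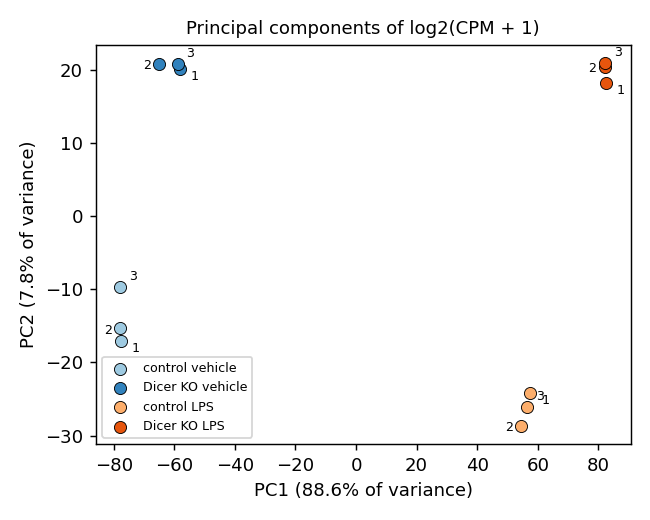
Principal components of log2 CPM, with 1 dot per library, labelled by its replicate number and coloured by group. PC1 (88.6% of the variance) parts LPS from vehicle and PC2 (7.80%) parts Dicer KO from control, and 1 library in each vehicle group lies away from the other replicates.

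The targeted gene, Dicer1 (ENSMUSG00000041415, GRCm38 chromosome 12, 104687742 to 104751952), was lower in every Dicer KO library than in every control library. In vehicle it measured 43.7 ± 1.44 CPM (SD, n = 3) in control and 19.7 ± 0.369 CPM in Dicer KO, 2.21-fold lower (log2 fold change −1.15 ± 0.06 SE, adjusted p = 1.47e-10). In LPS it measured 49.4 ± 2.84 and 15.5 ± 1.10 CPM, 3.18-fold lower (adjusted p = 2.14e-12). These counts cover the whole gene, and deletion of a floxed exon can leave most of the transcript. They therefore do not measure how much working Dicer1 remained. The largest genotype difference of any named gene was in Lyz2 (chromosome 10, 117277331 to 117282321), which encodes lysozyme M and is the locus that holds the LysM-Cre insertion. Lyz2 measured 5710 ± 335 CPM in control vehicle and 14.1 ± 1.49 CPM in Dicer KO vehicle, 405-fold lower (adjusted p = 4.42e-20). In LPS it measured 4060 ± 200 and 18.9 ± 2.38 CPM, 215-fold lower (adjusted p = 1.98e-19). The genotype comparisons are therefore between libraries that differ in both Dicer1 and Lyz2, although the titles give LysM-Cre to both genotypes. Apoe, the gene knocked out in all donors, was measured at low levels, 17.9 ± 1.91 CPM in control vehicle against 5.61 ± 0.610 CPM in Dicer KO vehicle (adjusted p = 3.49e-09). In LPS it measured 4.24 ± 0.622 and 1.20 ± 0.270 CPM (adjusted p = 9.03e-07). Lcor, a ligand-dependent nuclear receptor corepressor, was 2.81-fold higher in Dicer KO vehicle (5.86 ± 0.325 to 16.5 ± 0.957 CPM, adjusted p = 2.47e-10). It was 2.39-fold higher in Dicer KO LPS (14.2 ± 1.05 to 34.1 ± 1.36 CPM, adjusted p = 2.43e-10).

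**Figure D2:**
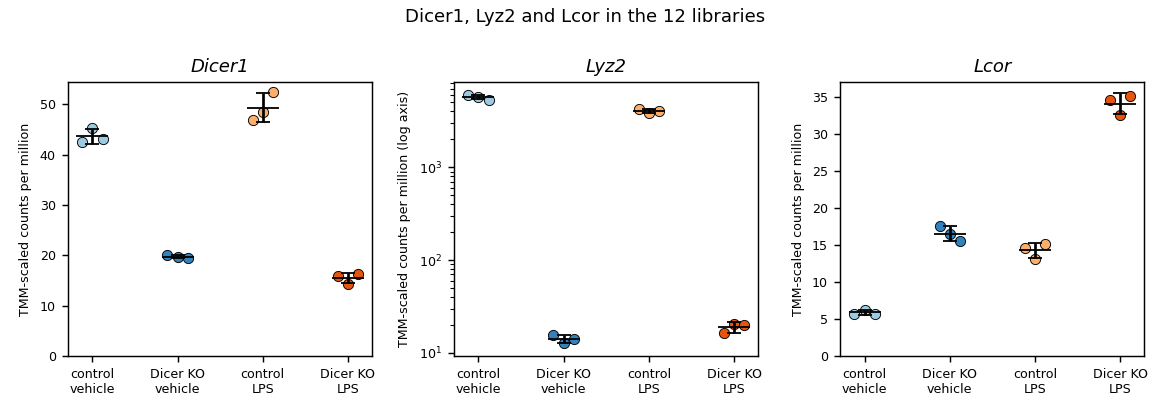
Dicer1, Lyz2 (log axis) and Lcor in CPM with TMM-scaled library sizes, with 1 dot per library and the mean ± SD of each group of 3. Dicer1 falls from 43.7 to 19.7 CPM and Lyz2 from 5710 to 14.1 CPM between control and Dicer KO in vehicle, while Lcor rises from 5.86 to 16.5 CPM.

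The comparison of Dicer KO with control in vehicle asks what differs in resting macrophages between genotypes that are unlike in both Dicer1 and Lyz2. Interferon-stimulated genes were higher in the resting Dicer KO cells. All 47 measured genes of the list rose (47 adjusted over the list alone), with a median log2 fold change of 2.29 (camera adjusted p = 7.34e-127; adjusted p = 0.0406 with an estimated correlation). Rsad2, which encodes the antiviral protein viperin, rose 18.6-fold, from 108 ± 10.7 to 2020 ± 446 CPM (SD, n = 3, adjusted p = 2.00e-09). Other members were Oas3, an RNA-activated antiviral enzyme (log2 fold change 2.29 ± 0.08 SE), Oasl2 (2.05), Dhx58, a sensor of viral RNA (1.82), and Bst2, which tethers virus particles (1.67). Of the other genes with the largest rises, Ifit3b (21-fold), Ifit1bl1 (20.0-fold), Ifi44 (16.5-fold), Ifi208 (15.7-fold), Gbp4 (14.4-fold), Ifi205 (13.0-fold) and Ifit3 (12.9-fold) are of interferon-inducible families, whose paralogs can share reads. The chemokine gene Ccl12 (21.3-fold, to 6.23 ± 1.32 CPM, with close paralogs) and Tnfsf10, the gene of the death ligand TRAIL (15.5-fold), rose as well. The library that stood apart was lowest of its group here, with a mean log2 level of the list of 7.52 in Dicer KO vehicle replicate 2 against 8.05 and 7.98 in the others and 5.43 to 5.63 in control vehicle.

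Targets of p53, the DNA damage response factor, also rose in resting Dicer KO cells, 19 of 24, with a median log2 fold change of 0.61 (20 adjusted over the list alone; camera adjusted p = 1.06e-06; adjusted p = 0.0643 with an estimated correlation). They included the cell cycle inhibitor gene Cdkn1a (0.91), Ccng1 (0.90), Aen (0.96) and Zmat3 (0.73), while Sesn1 and Fas fell. Textbook targets of the let-7 microRNAs rose in 15 of 23 cases (16 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 9.59e-07; adjusted p = 0.0243 with an estimated correlation). Ccnd2, a G1 cyclin (2.86), Igf2bp2, an RNA-binding protein (1.25), Cdc34 (0.99) and Arid3a (0.65) were among them, and Myc and Fas fell. Of 43 lysosomal genes 32 rose (32 adjusted over the list alone) and Ctsc, Ctsf and Ctsl fell, with a median of 0.32 (camera adjusted p = 9.59e-07; adjusted p = 0.330 with an estimated correlation). Examples were Ctsz (0.71), Tpp1 (0.66) and Idua (0.65). Of 21 endoplasmic reticulum stress genes 13 rose (14 adjusted over the list alone), among them the chaperone gene Hspa5 (0.68), Ddit3 (0.92) and Calr (0.72), while Herpud1, Trib3 and Ppp1r15a fell (camera adjusted p = 0.0110; adjusted p = 0.410 with an estimated correlation). That call was lost without the pair of libraries that stood apart (adjusted p = 0.0572).

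Of 31 LPS-induced cytokine and chemokine genes, 15 rose without LPS (15 adjusted over the list alone), among them Cxcl10 (3.59), Ccl4 (2.12) and Ccl3 (1.57). Il1b, Cxcl16 and Tnfsf9 fell. The median was 0.66 as fitted and 0.86 with genes of few counts at their bounds (camera adjusted p = 0.0436; adjusted p = 0.582 with an estimated correlation). The call was lost without Dicer KO vehicle replicate 1 (adjusted p = 0.0719) or Dicer KO LPS replicate 1 (adjusted p = 0.0522). Tnf rose from 22.9 ± 4.41 to 36.2 ± 0.968 CPM (SD, n = 3, adjusted p = 3.10e-05) and Nos2, the inducible nitric oxide synthase gene, from 1.02 ± 0.339 to 3.63 ± 2.11 CPM (adjusted p = 0.00715). Il1b fell from 15.7 ± 6.58 to 3.80 ± 1.86 CPM (adjusted p = 0.00344). Il6 had 1 count in control vehicle and 0 in Dicer KO vehicle, both under the floor, and Arg1 had too few counts in all groups to be tested.

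Hypoxia-inducible genes, glycolysis genes and ribosomal protein genes were lower in resting Dicer KO cells. Of 22 hypoxia and HIF targets 19 fell (19 adjusted over the list alone) and Hif1a itself rose, with a median log2 fold change of −0.80 (camera adjusted p = 2.41e-06; adjusted p = 0.582 with an estimated correlation). Vegfa, an angiogenic growth factor, fell from 133 ± 55.7 to 26.3 ± 12.6 CPM (5.03-fold, SD, n = 3, adjusted p = 0.00295). Egln3, an oxygen-sensing prolyl hydroxylase, fell from 70.0 ± 16.9 to 16.8 ± 9.76 CPM (4.12-fold, adjusted p = 0.00339). Ndrg1 (−0.98), Pfkfb3 (−0.73) and Pdk1 (−0.70) fell too. Of 20 glycolysis genes 16 fell (17 adjusted over the list alone), among them Gpi1 (−1.02), Pgam1 (−0.61) and Aldoa (−0.56), while Hk3 rose (median −0.59; camera adjusted p = 5.41e-05; adjusted p = 0.549 with an estimated correlation). The libraries that stood apart were the lowest of their groups for the hypoxia list, at a mean log2 level of 5.98 against 6.36 and 6.26 in control vehicle and 4.99 against 5.51 and 5.52 in Dicer KO vehicle. For glycolysis they were at 7.80 against 7.94 and 7.92, and at 7.12 against 7.5 and 7.5. Of 53 ribosomal protein genes 52 fell (52 adjusted over the list alone) by a small amount, with a median of −0.34 (camera adjusted p = 9.72e-15; adjusted p = 0.435 with an estimated correlation), for example Rpl3 (−0.43). Of 10 MHC class II genes 5 fell (7 adjusted over the list alone), which were Ciita, the master regulator of the class (−1.16), H2-Ab1 (−0.48), Cd74 (−0.40), H2-Eb1 and H2-Ob (camera adjusted p = 0.0470; adjusted p = 0.663 with an estimated correlation). The last call was lost with library totals (adjusted p = 0.0525) and without control vehicle replicate 1 (0.0622), control LPS replicate 2 (0.0524) or Dicer KO vehicle replicate 2 (0.173). The largest falls after Lyz2 were Cav1 (5.13-fold), Ankrd37 (5.12-fold, with 26.4% of its exons overlapped by an opposite-strand gene), Vegfa, Thbs1 (4.94-fold), Lrp2bp (4.57-fold, 8.0% overlapped), Plxdc2 (4.47-fold), Egln3, Il1b and Clec2i (4.02-fold). Thbs1, which encodes the matrix protein thrombospondin, was not called without control vehicle replicate 1 (adjusted p = 0.0536) or replicate 2 (adjusted p = 0.0525).

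Energy metabolism lists other than glycolysis were not called in vehicle. The median of the 76 nuclear-encoded oxidative phosphorylation genes was 0.02, with 19 higher and 11 lower (17 and 9 adjusted over the list alone; camera adjusted p = 0.940), and turned to −0.10 with library totals; the test pointed down at the median of 0.02. For fatty acid oxidation 10 of 29 genes rose, among them Hadha (0.46), and Acadm, Hadh, Echs1 and Eci2 fell (camera adjusted p = 0.704), with a median of 0.05 that turned to −0.08 with library totals. Within it, Cpt1a, which brings long-chain fatty acids into mitochondria, measured 163 ± 8.21 and 191 ± 19.2 CPM (SD, n = 3, log2 fold change 0.22, adjusted p = 0.00670). That call was lost without Dicer KO vehicle replicate 1 (0.16, adjusted p = 0.0515) and with library totals (0.10, adjusted p = 0.217). Hadhb, a subunit of the mitochondrial trifunctional protein, rose from 55.3 ± 1.73 to 77.2 ± 3.14 CPM (adjusted p = 1.06e-06). For the tricarboxylic acid cycle 12 of 24 genes rose, and Idh3b, Idh3g, Sdhd and Fh1 fell (camera adjusted p = 0.445). Mitochondrial biogenesis was not called either (4 of 19 higher and 3 lower, camera adjusted p = 0.783). The cholesterol synthesis list was not called with all libraries (5 of 24 higher, Tm7sf2 lower, camera adjusted p = 0.335), but was called, with a rise, without control vehicle replicate 3 (adjusted p = 0.0149), the library with the highest level of the list in its group (4.40 against 3.81 and 3.87). Abca1 measured 376 ± 71.0 and 395 ± 54.6 CPM (adjusted p = 0.685).

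In the vehicle comparison 3459 genes were higher and 2935 lower in Dicer KO out of 13837, of which 539 and 421 changed at least 2-fold (edgeR). The genes tested include 11810 protein-coding genes and 704 annotated as antisense to another gene. Of these 704, 249 were called here and 282 by genotype in LPS. With LPS in control and in Dicer KO 502 and 532 were, and in the interaction 156. Their counts can mirror the opposite-strand gene, since the strand setting is not given. With library totals in place of TMM, chosen after seeing the data, the counts were 2229 and 4577, because the median of all genes then shifted by −0.13.

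The comparison of Dicer KO with control in LPS asks the same of activated macrophages. Interferon-stimulated genes and cytokine genes were higher in Dicer KO cells after LPS, and cholesterol synthesis genes were lower. All 47 interferon-stimulated genes rose (47 adjusted over the list alone), with a median log2 fold change of 0.95 (camera adjusted p = 6.27e-19; adjusted p = 0.437 with an estimated correlation). Rsad2 rose from 2750 ± 381 to 25800 ± 995 CPM, 9.38-fold (SD, n = 3, adjusted p = 5.03e-09). The regulators Irf1 (1.25) and Irf9 (0.78) and the GTPase gene Irgm1 (1.37) rose as well. Of 31 cytokine and chemokine genes 22 rose (22 adjusted over the list alone) and Cxcl1 fell, with a median of 0.76 (camera adjusted p = 1.22e-05; adjusted p = 0.268 with an estimated correlation). Examples were Il1a (2.28, with 11.2% of its exons overlapped on the opposite strand), Cxcl9 (1.53), Il27 (1.01) and Cxcl16 (0.88). Il6 rose from 30.7 ± 2.22 to 54.7 ± 4.96 CPM (adjusted p = 3.43e-07) and Nos2 from 3040 ± 174 to 5930 ± 152 CPM (adjusted p = 0.00113). Tnf measured 1460 ± 43.4 and 1510 ± 78.3 CPM (log2 fold change 0.05, adjusted p = 0.644; −0.30 and adjusted p = 0.00255 with library totals). Il1b measured 1810 ± 134 and 1860 ± 122 CPM (adjusted p = 0.905). Of 38 genes of the TLR4 and NF-kappaB pathway 24 rose, among them Tlr4 (1.18), Socs1 (1.12), Myd88 (0.78) and Tab2 (0.67), and Ticam2, Irak1, Irak3 and Ikbkg fell (camera adjusted p = 0.0251; adjusted p = 0.330 with an estimated correlation). The median of that list, 0.22, turned to −0.13 with library totals, where it was not called (adjusted p = 0.566).

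Cholesterol synthesis genes were lower in Dicer KO than in control cells after LPS. Of 24 genes 21 fell (22 adjusted over the list alone) and 0 rose, with a median log2 fold change of −0.95 (camera adjusted p = 3.97e-06; adjusted p = 0.587 with an estimated correlation). Fdps (−2.22), Lss (−1.71), Mvd (−1.58) and Acat2 (−1.13), enzymes of the pathway, were among them. Of 22 cholesterol efflux genes and targets of the LXR nuclear receptors, 11 rose and 6 fell (camera adjusted p = 0.0465, and 0.268 with an estimated correlation). Abca1, the cholesterol exporter gene, rose from 185 ± 9.30 to 561 ± 20.1 CPM, 3.03-fold (SD, n = 3, adjusted p = 8.46e-07), with Ch25h (2.18), Abcg1 (1.66) and Mylip (1.06), while Srebf1 (−0.85) fell. Scd2, a fatty acid desaturase in the same list, fell 8.72-fold, from 113 ± 5.01 to 13.0 ± 0.565 CPM (adjusted p = 2.48e-07). The median of the efflux list, 0.17, turned to −0.18 with library totals, and the call was lost there (adjusted p = 0.118) and without control vehicle replicate 3 (0.0883) or control LPS replicate 2 (0.0593).

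Lysosomal genes rose in 35 of 43 cases after LPS (35 adjusted over the list alone), with Neu1 and Tfeb lower and a median of 0.49 (camera adjusted p = 4.29e-09; adjusted p = 0.268 with an estimated correlation). Examples were Gla (1.20) and Tpp1 (0.90). Textbook let-7 targets rose in 16 of 23 cases and fell in 2 (16 and 2 adjusted over the list alone), E2f6 among the latter, with a median of 0.59 (camera adjusted p = 1.22e-05; adjusted p = 0.0406 with an estimated correlation). They included Arid3b (1.49), Igf2bp2 (1.28) and Plagl2 (0.61). Textbook targets of other macrophage microRNAs rose in 23 of 38 cases and fell in 6 (23 and 7 adjusted over the list alone). Bach1, a repressor of antioxidant genes (2.30), and Dusp1, a MAP kinase phosphatase (1.17), were among those that rose. The camera adjusted p was 0.000517, and 0.330 with an estimated correlation. This list shares members with the TLR4 and cholesterol efflux lists.

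Hypoxia targets, glycolysis genes and ribosomal protein genes were lower in Dicer KO cells after LPS too. Of 22 hypoxia targets 16 fell (17 adjusted over the list alone) and Pfkfb3 rose, with a median of −1.12 (camera adjusted p = 3.97e-06; adjusted p = 0.582 with an estimated correlation). Egln3 fell 18-fold, from 45.2 ± 10.4 to 2.51 ± 0.755 CPM (SD, n = 3, adjusted p = 0.000447) and Vegfa fell 8.47-fold. Egln1 (−1.53), Car9 (−1.25), Ndrg1 (−1.16) and Pfkfb4 (−1.04) fell. Of 20 glycolysis genes 14 fell, among them Gpi1 (−1.37) and Pkm (−0.47), and Hk1, Hk3 and Pfkfb3 rose (median −0.64; camera adjusted p = 0.00516; adjusted p = 0.663 with an estimated correlation). Of 53 ribosomal protein genes 39 fell (40 adjusted over the list alone) and Rps24 rose, with a median of −0.23 (camera adjusted p = 0.000139; adjusted p = 0.760 with an estimated correlation). The list of nuclear-retained RNA and histone transcripts, held as a sign of RNA quality, was lower in Dicer KO LPS libraries as well. Of its 9 members 7 fell, among them Neat1 (−1.14) and Gas5 (−0.78), and Rn7sk rose (camera adjusted p = 0.0211; adjusted p = 0.413 with an estimated correlation), a call lost with library totals (adjusted p = 0.0741).

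The largest rise in LPS was in Slc40a1, the iron exporter ferroportin, from 1.44 ± 0.224 to 27.4 ± 1.48 CPM, 19-fold (SD, n = 3, adjusted p = 9.58e-14). It was followed by Olfml3 (15.8-fold), Ifit1bl1 (15.1-fold), Tgtp1 (13.6-fold), Dnase1l3 (11.1-fold), Ifit3b (9.87-fold), Rsad2, Apol9a (8.94-fold), Serpina3f (8.42-fold) and Spsb1 (8.32-fold), of which Ifit1bl1, Tgtp1, Ifit3b, Apol9a and Serpina3f have close paralogs that can share reads. The largest falls after Lyz2 and Egln3 were Clec2i (12.9-fold), Mgarp (10.3-fold), Lrp2bp (9.50-fold, 8.0% overlapped on the opposite strand), Selenbp1 (9.03-fold), Arrb1 (8.92-fold), Scd2, Vegfa and Rcor2 (7.84-fold). Cpt1a was higher in Dicer KO LPS cells, at 179 ± 2.23 against 110 ± 3.74 CPM (log2 fold change 0.70, adjusted p = 4.03e-08). Hadhb measured 38.4 ± 2.15 and 40.7 ± 1.62 CPM (−0.09, adjusted p = 0.252; −0.44 and adjusted p = 5.82e-06 with library totals). The fatty acid oxidation list had 5 of 29 genes higher, which were Cpt1a, Hadha, Acaa1a, Eci2 and Etfdh, and 11 lower (camera adjusted p = 0.495). Not called either were oxidative phosphorylation (19 of 76 higher and 10 lower, camera adjusted p = 0.803), the tricarboxylic acid cycle (8 of 24 higher and 8 lower, camera adjusted p = 0.563) and p53 targets (8 of 24 higher and 6 lower, camera adjusted p = 0.704). With library totals the median of oxidative phosphorylation turned from 0.09 to −0.26, with 2 genes higher and 62 lower, and that of the tricarboxylic acid cycle from 0.06 to −0.29, with 0 higher and 19 lower. In all, 3983 genes were higher and 3741 lower in Dicer KO LPS, of which 844 and 918 changed at least 2-fold. With library totals, chosen after seeing the data, the counts were 1885 and 7626, with a shift of the median of all genes of −0.35.

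**Figure D3:**
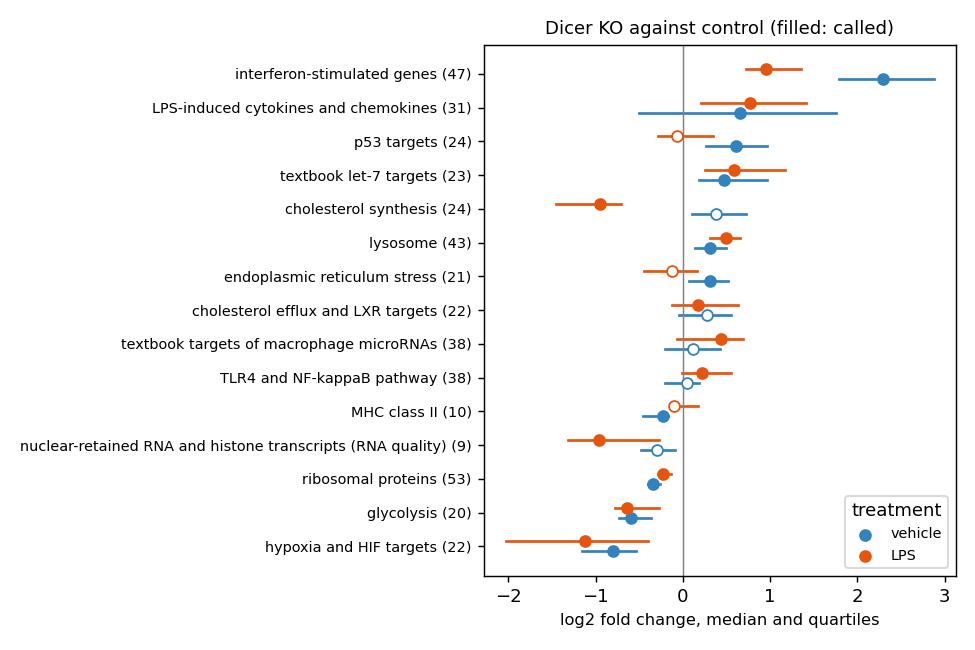
Median log2 fold change between Dicer KO and control of 15 gene lists, with quartiles of the members as bars, in vehicle and in LPS; filled symbols passed camera at the preset correlation. Interferon-stimulated genes lie at 2.29 and 0.95, hypoxia targets at −0.80 and −1.12, and the LPS medians of the TLR4 and the cholesterol efflux list, 0.22 and 0.17, turn to −0.13 and −0.18 with library totals, as do the vehicle medians of the macrophage microRNA targets, from 0.12 to −0.006, and of the TLR4 list, from 0.05 to −0.08.

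The genotype differences in vehicle and in LPS, which share no libraries, overlapped. Of the genes called, 2222 were higher in Dicer KO in both treatments and 1629 were lower in both. Independent calls, equally likely for every gene, would give 996 and 794. Both comparisons come from the same model with a shared estimate of the spread, and vehicle and LPS cultures may have shared mice. The overlap is thus no independent replication. Among the 4397 genes called in both, 87.6% had the same direction. Across all genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.53 and Spearman's rho 0.52.

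The comparison of LPS with vehicle in control cells gives the LPS response at 6 h. All 31 cytokine and chemokine genes rose (31 adjusted over the list alone), with a median log2 fold change of 5.98 as fitted and 5.73 with genes of few counts at their bounds (camera adjusted p = 2.57e-27; adjusted p = 0.0168 with an estimated correlation). Tnf rose 63.8-fold, from 22.9 ± 4.41 to 1460 ± 43.4 CPM (SD, n = 3, adjusted p = 1.38e-18), Il1b 115-fold, to 1810 ± 134 CPM, and Nos2 2940-fold, to 3040 ± 174 CPM. Il27 (5.53) and Tnfsf9 (5.65) were other members. Il6 rose by a ratio of 2240, with a 95% counting interval of 402 to 88600. Of 38 TLR4 and NF-kappaB pathway genes 30 rose, among them the feedback regulators Socs3 (9.12), Nfkbia (4.30) and Zc3h12a (3.12), and Tlr4, Irak1, Map3k7, Tab1 and Inpp5d fell (median 1.48; camera adjusted p = 1.95e-18; adjusted p = 0.00327 with an estimated correlation). All 47 interferon-stimulated genes rose (47 adjusted over the list alone), with a median of 3.34 and with Ifih1, a cytosolic RNA sensor (4.0), and Trim30a (2.74) as examples (camera adjusted p = 9.87e-29; adjusted p = 0.360 with an estimated correlation).

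Of 24 cholesterol synthesis genes 20 rose in control cells after LPS, among them Fdps (4.02) and Mvd (2.27), and Dhcr7 and Ebp fell (median 2.10; camera adjusted p = 0.0110; adjusted p = 0.789 with an estimated correlation). Glycolysis genes rose in 16 of 20 cases, with Pfkfb3 (4.39), the lactate transporter gene Slc16a1 (3.02) and Hk1 (1.67) as examples, and Gpi1, Pfkm and Aldoc fell (median 0.62; camera adjusted p = 0.0474; adjusted p = 0.789 with an estimated correlation). The glycolysis call was lost without control vehicle replicate 3 (adjusted p = 0.0553), control LPS replicate 2 (0.0593) or Dicer KO LPS replicate 1 (0.0513), and with the replicate number as a block (0.0516). Of 47 proliferation genes 39 fell, among them Cenpa (−3.75) and Mcm7 (−2.52), while Ccnd2 (7.33), Mki67, Ccne1, Tpx2 and Ccnd3 rose (median −1.73; camera adjusted p = 0.0198; adjusted p = 0.852 with an estimated correlation). Control vehicle replicate 3 was the highest of its group for proliferation, at 4.47 against 3.83 and 3.82, and with library totals the proliferation call was lost (adjusted p = 0.165). Of 43 lysosomal genes 28 fell and 10 rose, with Atp6v0d2 (−3.07), Lipa (−2.27) and Npc1 (−2.03) as examples (median −0.43; camera adjusted p = 0.0224; adjusted p = 0.641 with an estimated correlation). Cholesterol efflux genes fell in 12 of 22 cases and rose in 6, with Abca1 at −1.02 (median −0.38, camera adjusted p = 0.0407, 0.268 with an estimated correlation). This call was lost without control LPS replicate 2 (adjusted p = 0.0571) or 3 (0.0574). Apoe, which is knocked out in all donors and is not in this list, had its low counts fall by −2.07. Of 7 microRNA host transcripts Mir155hg, Mir22hg, Mir99ahg and Dleu2 rose and Mirt1 fell (camera adjusted p = 0.0465; adjusted p = 0.582 with an estimated correlation), a call lost without control LPS replicate 2 (0.0571) or Dicer KO vehicle replicate 2 (0.0742), without both libraries that stood apart (0.107) and with the replicate block (0.0681).

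Of genes with more than 3 counts in vehicle, Nos2 and Cxcl9, a chemokine gene (1600-fold, from 0.110 ± 0.0642 to 185 ± 23.8 CPM, SD, n = 3, adjusted p = 5.16e-18), were among the largest rises. Genes with 1 to 3 counts in vehicle rose by ratios of 14100 for Lipg (95% counting interval 2530 to 558000), 6430 for the endothelin gene Edn1 (1780 to 53100), 3510 for Il12b (971 to 29000) and 2690 for Mir155hg (745 to 22200). Those with 0 counts rose at least 499-fold (Ptx3), 469-fold (Ifitm7, with 10.9% of its exons overlapped on the opposite strand and close paralogs) and 466-fold (Vgf). The largest falls were Angptl4 (at least 82.5-fold lower), Rasgrp3 (log2 fold change −7.61), Slco2b1 (130-fold, 9.20% overlapped), St6gal1 (126-fold), Cd28 (88.7-fold), Slc40a1 (84.4-fold) and Zfyve28 (68.9-fold). Sox4 (54.6% overlapped), Nat8l and Pcyt1b, with 1 to 3 counts in LPS, fell by ratios with 95% counting intervals of 56.9 to 811, 33.2 to 475 and 31.7 to 454. Dicer1 itself differed by 0.18 (adjusted p = 0.0110), which was not called without control LPS replicate 3 (adjusted p = 0.0725) and turned to −0.34 with library totals (adjusted p = 4.27e-05). Cpt1a (−0.57), Hadhb (−0.44) and Lyz2 (−0.49) fell, and Lcor rose (1.28). In all, 5258 genes rose and 5690 fell, of which 2465 and 2781 changed at least 2-fold. With library totals, chosen after seeing the data, the counts were 3066 and 8737, with a shift of the median of all genes of −0.52.

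The same comparison in the Dicer KO group, where Dicer1 counts over the whole gene were lower, gives its LPS response. All 31 cytokine genes rose (31 adjusted over the list alone), with a median log2 fold change of 6.14 as fitted and 5.82 at bounds (camera adjusted p = 1.96e-27; adjusted p = 0.00245 with an estimated correlation). Tnf rose 41.8-fold, from 36.2 ± 0.968 to 1510 ± 78.3 CPM (SD, n = 3, adjusted p = 2.98e-18), Il1b 484-fold, Nos2 1610-fold and Il27 by 6.16 on the log2 scale. Of 38 TLR4 and NF-kappaB pathway genes 29 rose and 6 fell (median 1.66; camera adjusted p = 1.04e-18; adjusted p = 0.00245 with an estimated correlation), with Socs3 at 9.89. All 47 interferon-stimulated genes rose (47 adjusted over the list alone; median 2.17; camera adjusted p = 2.37e-13; adjusted p = 0.549 with an estimated correlation), with Irf1 at 2.41. Of 24 p53 targets 19 fell, among them Sesn1 (−5.46) and Zmat3 (−2.33), and Mdm2 (2.04), Cdkn1a, Fas and Btg2 rose (median −1.17; camera adjusted p = 0.0172; adjusted p = 0.390 with an estimated correlation). Proliferation genes fell in 38 of 47 cases and rose in 6 (median −1.92; camera adjusted p = 0.0170; adjusted p = 0.852 with an estimated correlation), a call lost with library totals (adjusted p = 0.251). Textbook let-7 targets rose in 13 of 23 cases and fell in 8 (camera adjusted p = 0.0470; adjusted p = 0.390 with an estimated correlation), with a median of 0.46 that turned to −0.28 with library totals. That call was lost without control vehicle replicate 3 (adjusted p = 0.0772) or Dicer KO vehicle replicate 3 (0.0510). Cholesterol synthesis (13 of 24 higher, Dhcr7, Tm7sf2 and Ebp lower, camera adjusted p = 0.728) and glycolysis (12 of 20 higher, Gpi1, Pfkm and Aldoc lower, camera adjusted p = 0.0664) were not called, and their medians of 0.60 and 0.52 turned to −0.15 and −0.23 with library totals. Glycolysis was called without Dicer KO vehicle replicate 2 (adjusted p = 0.0462), Dicer KO vehicle replicate 3 (0.0302) or Dicer KO LPS replicate 3 (0.0497).

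Of genes with more than 3 counts in Dicer KO vehicle, Edn1 (4180-fold) and Slamf1, a receptor of immune cells (2300-fold), had some of the largest rises with LPS. Genes with 0 counts in vehicle rose at least 3050-fold (Cd38), 1840-fold (Steap4), 1140-fold (Il6), 945-fold (Ptx3), 686-fold (Col27a1) and 302-fold (Ifitm7, 10.9% overlapped on the opposite strand). Serpinb2 rose by a ratio of 3100 (95% counting interval 555 to 122000). Rasgrp3 (211-fold), Sox4 (181-fold, 54.6% overlapped), Engase (109-fold, 8.30% overlapped) and Lpin1 (84.3-fold) fell most, with Angptl4 at least 133-fold lower. Vash2, Etl4, Pald1, Bmyc (62.8% overlapped) and Dnah11, with few counts in LPS, fell by ratios of 130 (35.8 to 1080), 127 (34.9 to 1050), 113 (31.0 to 936), 100 (27.5 to 831) and 90.5 (30.7 to 440). Hadhb fell by 1.01 on the log2 scale (adjusted p = 7.43e-12), Dicer1 fell by 0.35 (adjusted p = 0.000324), Apoe fell by 2.22 and Lcor rose (1.05). Cpt1a differed by −0.09 (adjusted p = 0.180; −0.84 and adjusted p = 5.02e-10 with library totals). Abca1 rose (0.51, adjusted p = 0.00331) but was at −0.24 with library totals (adjusted p = 0.107). Lyz2 rose (0.42, adjusted p = 0.00106) but was at −0.33 with library totals (adjusted p = 0.00424). In all, 5173 genes rose and 5905 fell, of which 2615 and 3220 changed at least 2-fold. With library totals, chosen after seeing the data, the counts were 2637 and 9623, with a shift of the median of all genes of −0.75.

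The interaction asks whether the LPS response differs between the genotypes. Interferon-stimulated genes and cholesterol synthesis genes had less positive log2 responses to LPS in Dicer KO than in control cells. For interferon-stimulated genes the response was lower for 44 of 47 genes (44 adjusted over the list alone) and higher for 0, with a median difference of −1.24 (camera adjusted p = 1.30e-37; adjusted p = 0.324 with an estimated correlation), for example Oas3 (−1.70) and Ifi204 (−1.46). Their mean log2 level in Dicer KO cells was 7.52 to 8.05 in vehicle and 10.4 in LPS, against 5.43 to 5.63 and 9.14 to 9.30 in control. For cholesterol synthesis it was lower for 21 of 24 genes (21 adjusted over the list alone) and higher for 0, with a median of −1.53 (camera adjusted p = 6.19e-11; adjusted p = 0.435 with an estimated correlation), for example Fdps (−2.25) and Mvd (−1.56). The libraries that stood apart were the highest of their groups for this list, at 4.40 against 3.81 and 3.87 in control vehicle and 4.67 against 4.20 and 4.33 in Dicer KO vehicle. Endoplasmic reticulum stress genes (14 of 21 lower, Ppp1r15a higher, median −0.42; camera adjusted p = 0.000115; adjusted p = 0.268 with an estimated correlation) and p53 targets (15 of 24 lower, Mdm2, Fas, Plk2 and Btg2 higher, median −0.57; camera adjusted p = 0.00129; adjusted p = 0.268 with an estimated correlation) also had more negative log2 responses. So did the antioxidant response list (11 of 23 lower, Pgd higher, median −0.32; camera adjusted p = 0.0123; adjusted p = 0.626 with an estimated correlation), with Hmox1 (−1.06) and Gsr (−0.76).

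**Figure D4:**
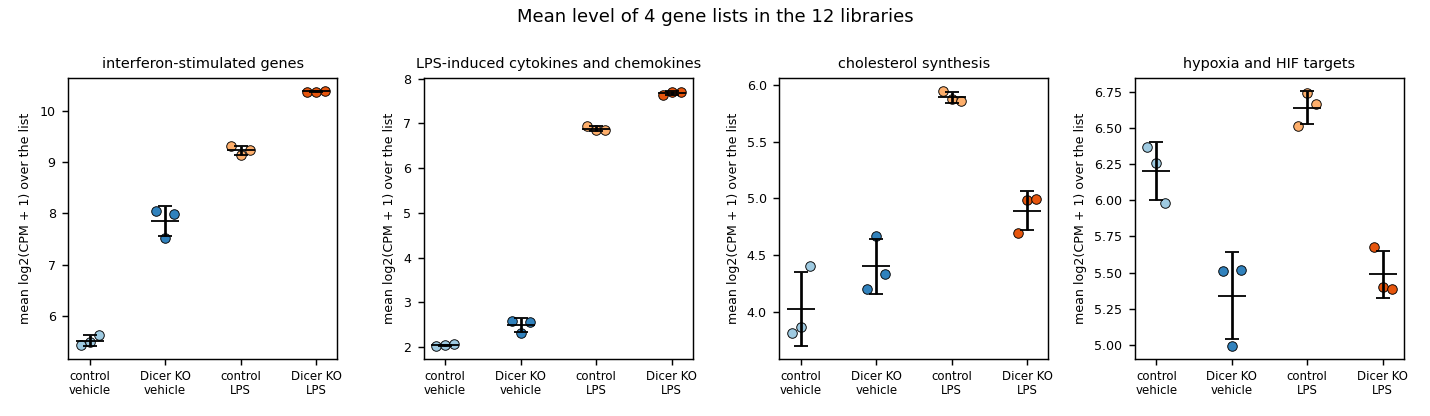
Mean log2(CPM + 1) of the members of 4 gene lists, with 1 dot per library and the mean ± SD of each group of 3. Interferon-stimulated genes lie between 7.52 and 8.05 in Dicer KO vehicle against 5.43 to 5.63 in control vehicle, and control vehicle replicate 3 and Dicer KO vehicle replicate 2 lie apart for hypoxia targets and cholesterol synthesis.

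Genes of alternative activation had a more positive log2 response in Dicer KO cells, 13 of 22 and 0 the other way (14 and 1 adjusted over the list alone), with a median difference of 0.37 (camera adjusted p = 8.70e-05; adjusted p = 0.0406 with an estimated correlation). Examples were the transcription factor gene Klf4 (1.94), Tgm2 (1.04), Stab1 (0.47) and Trem2 (0.36). Lists called with medians that turn with library totals were lysosome (0.22, to −0.003), TLR4 and NF-kappaB (0.12, to −0.11), textbook macrophage microRNA targets (0.14, to −0.09) and ribosomal proteins (0.11, to −0.11). More positive responses were seen in 23 of 43 lysosomal genes against 5 more negative, 15 of 38 TLR4 pathway genes against 5, 17 of 38 microRNA targets against 9 and 8 of 53 ribosomal protein genes against 0. Their camera adjusted p values were 0.00516, 0.0242, 0.0198 and 0.0170, and the adjusted p values with an estimated correlation were 0.582, 0.330, 0.516 and 0.852. None of these 4 lists was called with library totals (adjusted p = 0.165, 0.274, 0.0780 and 0.566). The ribosomal call was also lost without control vehicle replicate 1 (adjusted p = 0.0734) or Dicer KO LPS replicate 1 (0.0643). The cytokine list was not called (8 of 31 higher and 7 lower, camera adjusted p = 0.465), nor was fatty acid oxidation (Cpt1a and Eci2 of 29 higher and 9 lower, camera adjusted p = 0.223; adjusted p = 0.041 with library totals).

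Among the largest differences, Ciita (log2 difference 3.27 ± 0.18 SE, adjusted p = 9.24e-10) fell with LPS in control, from 9.91 ± 1.03 to 2.09 ± 0.185 CPM (SD, n = 3), and rose in Dicer KO, from 4.43 ± 0.0515 to 9.0 ± 0.344 CPM. Spsb1 (3.28), a negative regulator of inducible nitric oxide synthase, Il1a (3.08, 11.2% overlapped on the opposite strand) and Kmo (3.25), an enzyme of tryptophan breakdown, also had more positive responses in Dicer KO, as did Htr2b (3.14, 11.8% overlapped) and Thbs1 (3.09, adjusted p = 0.0282). Thbs1 was not called without most single libraries (adjusted p = 0.0512 to 0.0636). Arrb1, an arrestin of receptor signalling (−2.75 ± 0.15 SE, adjusted p = 1.46e-09), fell from 292 ± 16.6 to 38.5 ± 6.12 CPM in control and from 220 ± 5.60 to 4.31 ± 0.299 CPM in Dicer KO. Ifi44 (−2.68), Ifi205 (−2.52) and Olfr56 (−2.56) had smaller rises in Dicer KO. Cd38, Syt7, Asprv1, Dmtn, Lipg, Pald1, Bmyc, Heatr9 and Cobll1 are among the largest as well, but had 0 or few counts in at least 1 group, where the fitted difference is no bound. Abca1 (1.53, adjusted p = 7.07e-05), Il1b (2.07, adjusted p = 0.0112), Cpt1a (0.48, adjusted p = 0.000493) and Lyz2 (0.91, adjusted p = 2.76e-05) had more positive responses in Dicer KO. Hadhb (−0.57, adjusted p = 3.46e-05), Tnf (−0.61, adjusted p = 0.00130) and Dicer1 (−0.52, adjusted p = 0.000349) had more negative ones. Apoe (adjusted p = 0.707), Il6 (0.305), Lcor (0.145; 0.00462 with library totals) and Nos2 (0.212; 0.000175 without Dicer KO vehicle replicate 2) were not called. In all, the response was more positive in Dicer KO for 2067 genes and more negative for 2602. With library totals, chosen after seeing the data, the counts were 997 and 5136, with a shift of the median of all genes of −0.23.

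Genes with microRNA seed sites were compared to ask whether targets of macrophage microRNAs were higher in Dicer KO cells. Genes are not independent replicates. The SEs and model p-values here treat them as such and hold no spread between libraries, so a call describes these libraries only. In LPS, the 800 genes with a site for miR-142-3p were higher than genes without by 0.11 ± 0.03 (log2, SE, model adjusted p = 0.00470), a difference above all 139 shuffled sites. The call was lost with 8-base sites (adjusted p = 0.170) and among genes above 10 CPM (0.0884), and in vehicle the difference was 0.02. For let-7 sites the difference was 0.06 ± 0.02 in vehicle (model adjusted p = 0.0729; 0.0378 with 8-base sites) and 0.05 in LPS (model adjusted p = 0.309), both above all 104 shuffled sites. Comparison families reached the other end, with miR-122 at −0.07 in LPS (model adjusted p = 0.0729), below all 104 shuffled sites, and miR-375 at percentile 1.0 in vehicle. In LPS, sites for miR-181 gave 0.04 ± 0.02 (model adjusted p = 0.256), above all 200 shuffled sites, and sites for miR-19 lay at percentile 98.0. Macrophage families above the central 95% of their shuffled sites were 4 of 22 in LPS and 1 of 22 in vehicle. In a joint fit the difference per macrophage site was 0.0116 ± 0.0038 (SE) in LPS and 0.0046 ± 0.0031 in vehicle, against −0.0176 ± 0.0092 and −0.0063 ± 0.0076 per comparison site. Sites for miR-10 gave −0.02 in vehicle and −0.02 in LPS, at percentiles 43.5 and 47.0 of the shuffled sites. Differences were positive for 15 of 22 macrophage families in vehicle and 17 of 22 in LPS, and for 2 of 6 comparison families in both treatments. The shuffled sites were too few for a single family to pass after adjustment of the ranks, so the ranks are given without a call.

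**Figure D5:**
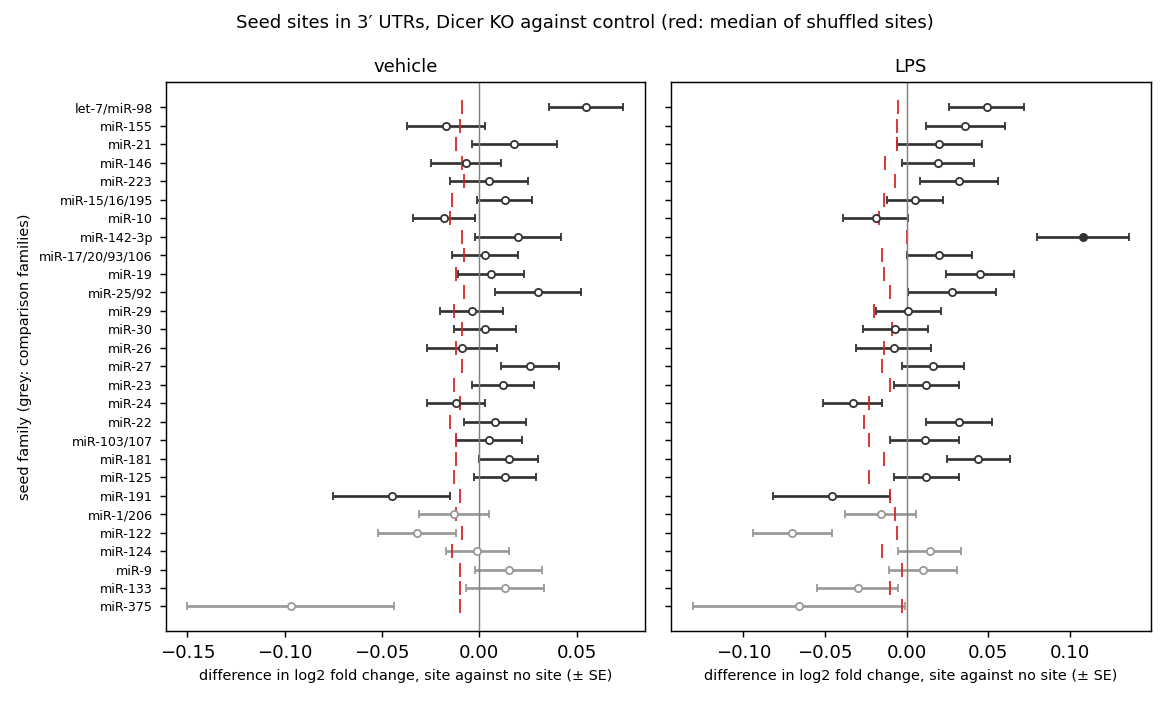
Difference in log2 fold change between genes with and without a seed site for 28 microRNA families, in vehicle and in LPS. Bars are SE across genes, red marks are the medians of the shuffled sites, and filled symbols passed the model test. Only miR-142-3p in LPS, at 0.11, is filled, and let-7 lies above its shuffled sites in both treatments.

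Markers of other cell types were fixed as lists because marrow cultures can hold them, and none was called by genotype in either treatment with all libraries. The camera adjusted p values in vehicle and LPS were 0.467 and 0.634 for 16 neutrophil genes, 0.214 and 0.495 for 3 B lymphocyte genes, 0.0923 and 0.0692 for 8 dendritic cell genes, 0.783 and 0.0635 for 3 mast cell genes, 0.472 and 0.445 for 5 endothelial genes, and 0.3 and 0.0598 for 9 genes of osteoclast differentiation. In LPS the dendritic cell list was called without control vehicle replicate 3 (adjusted p = 0.0499), control LPS replicate 3 (0.05) and with library totals (0.0101; 0.041 in vehicle). The mast cell list in LPS was called without control vehicle replicate 3 (adjusted p = 0.0499) or control LPS replicate 1 (0.0474) and with library totals (0.0205). The osteoclast list in LPS was called without control LPS replicate 3 (0.0472), Dicer KO vehicle replicate 3 (0.0493) or Dicer KO LPS replicate 3 (0.0323) and with library totals (0.0298). The 22 macrophage identity genes, Lyz2 included, were not called (camera adjusted p = 0.347 in vehicle and 0.210 in LPS; 0.0240 in LPS with library totals). Also not called by genotype in either treatment were alternative activation (0.127 and 0.0748), proliferation (0.923 and 0.495), the small RNA machinery (0.571 and 0.445), microRNA host transcripts (0.495 and 0.238), the antioxidant response (0.187 and 0.324) and mitochondrial biogenesis (0.783 and 0.785), as camera adjusted p. With library totals the antioxidant response was called in LPS (adjusted p = 0.0325), and its median turned from 0.07 to −0.28, with 1 gene higher and 19 lower. Called by genotype in LPS but not in vehicle were TLR4 (0.605 in vehicle), cholesterol synthesis (0.335), cholesterol efflux (0.0696), the macrophage microRNA targets (0.0635) and nuclear-retained RNA (0.220). In vehicle but not in LPS they were p53 targets (0.704 in LPS), endoplasmic reticulum stress (0.345) and MHC class II (0.906), which does not by itself show a difference between treatments. The macrophage microRNA targets were called in vehicle without control vehicle replicate 1 (adjusted p = 0.0333) or 2 (0.0392). Median, mean and test differed in sign only in lists that were not called, among them macrophage identity, where the median in vehicle was 0.06 and the mean −0.20. Of all 155 list tests 47 were called at the preset correlation and 8 with an estimated one, which were the 2 with cytokines and the 2 with the TLR4 pathway under LPS, let-7 targets by genotype in vehicle and in LPS, interferon-stimulated genes by genotype in vehicle, and alternative activation in the interaction.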

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

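The tests on other macrophage genes, on Lyz1, on carry-over, on scaling, on Ifnb1 and on reads from both strands were chosen only after the results were seen, while the splits of the samples and the test of the region around Lyz2 were chosen before.

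The LPS response differed between the genotypes by the interaction test, with 2067 genes more positive and 2602 more negative in Dicer KO, 4669 together. Of 100 splits drawn from the 200 possible, 5 gave as many genes, the real one included, and the highest other gave 8218, so chance is not excluded by this count. The other 4 as large kept the genotypes apart within LPS or within vehicle, so genotype differences entered them as an interaction. The 75 that kept them apart in neither gave at most 0. Splits that mix the genotypes add their differences to the spread within groups, so a 0 there was near certain beforehand and decides nothing. For the 4 pairwise comparisons, 3 against 3 libraries give 10 splits, too few for a share under 0.05. Their real counts were 6394 and 7724 genes for genotype in vehicle and LPS, and 10948 and 11078 for LPS in control and Dicer KO. Only 1 split in each gave as many genes, the real one, and the highest of the others was 0. These others mix the compared groups too, so their 0 does not bear on chance either.

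Interaction differences of named genes (log2, response in Dicer KO minus that in control) were 5.31 for Cd38, 4.24 for Syt7, 3.38 for Asprv1, 3.28 for Spsb1, 3.27 for Dmtn, 3.27 for Ciita, 3.25 for Kmo, 3.14 for Htr2b, 3.09 for Thbs1 and 3.08 for Il1a. On the other side they were −4.41 for Lipg, −3.45 for Pald1, −3.06 for Bmyc, −2.89 for Heatr9, −2.81 for Cobll1, −2.75 for Arrb1, −2.68 for Ifi44, −2.56 for Olfr56 and −2.52 for Ifi205. Those of Cd38, Syt7, Asprv1, Dmtn, Lipg, Pald1, Bmyc, Heatr9 and Cobll1 rest on few or no counts in some group and are no bounds. Thbs1 was called with all libraries and without control vehicle replicate 3 or Dicer KO vehicle replicate 1 or 2, and the other 9 removals gave adjusted p values of 0.0512 to 0.0636. Syt7 was not called without control vehicle replicate 2 (adjusted p = 0.191) or 3 (0.0576) or without any of the Dicer KO vehicle replicates (0.0601, 0.0557 and 0.0626). Cobll1 was not called without control vehicle replicate 1 (adjusted p = 0.0877) or 2 (0.0896) or Dicer KO vehicle replicate 2 (0.185), and Lipg not without control vehicle replicate 3 (0.0619). The genes reported in every comparison that differed were Abca1 (1.53), Il1b (2.07), Lyz2 (0.91), Cpt1a (0.48), Dicer1 (−0.52), Hadhb (−0.57) and Tnf (−0.61).

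Interaction medians of called lists were −1.24 for interferon-stimulated genes, −1.53 for cholesterol synthesis, −0.57 for p53 targets, −0.42 for endoplasmic reticulum stress, −0.32 for the antioxidant response and 0.37 for alternative activation. With an estimated correlation the first 5 lost the call (adjusted p = 0.324, 0.435, 0.268, 0.268 and 0.626) and alternative activation kept it (0.0406). The medians of lysosome (0.22), textbook macrophage microRNA targets (0.14), the TLR4 pathway (0.12) and ribosomal proteins (0.11) turn in sign with library totals, and these calls were lost with an estimated correlation too (adjusted p = 0.582, 0.516, 0.330 and 0.852).

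Lyz2 was 405-fold lower in Dicer KO than in control vehicle and 215-fold lower in LPS, although the titles give LysM-Cre, which sits in this locus, to both genotypes, while the names of the control files mark it as wildtype. A loss of macrophage identity in the cultures would lower the other identity genes as far, but the lowest of the 21 others was −2.92 (Marco in LPS), and their medians were 0.09 in vehicle and 0.29 in LPS. Reads moved to the paralog Lyz1 are excluded as well, since Lyz1 and Lyz2 together held at most 2.13% of their control level in Dicer KO. Whether a different chromosome segment around Lyz2 plays a part cannot be told apart with 39 tested genes nearby. In vehicle 3 of them changed at least 2-fold, against 957 of 13798 elsewhere (two-sided Fisher exact p = 0.75). In LPS 7 did, against 1755 of 13798 (p = 0.332, same exact test). Among the changed genes nearby were Hmga2 of the let-7 list in both treatments and Mdm2 of the p53 list in LPS. Titles with LysM-Cre on a single copy would leave an intact Lyz2 copy in both genotypes. Lyz2 in Dicer KO was at 0.247% of control in vehicle and 0.465% in LPS. That is far less than an intact copy would leave if nothing else lowered it, which argues against the titles. A candidate explanation that stays open is that the genotypes differ in the number of LysM-Cre copies, controls without any included. It was untested because no count covers the insertion. Effects of Dicer loss and of such a difference are not separable in these groups.

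Interferon-stimulated genes were higher in resting Dicer KO cells, with a median of 2.29. Carry-over of RNA or reads from LPS libraries is excluded as the whole cause, since the 47 genes would need a median share of 30.6% (quartiles 14.4 to 41.9) while the 31 LPS-induced cytokine genes allow 0.338% (−0.723 to 1.80). Scaling is excluded too, since the median was 2.17 with library totals. More interferon beta transcript in these cultures fits the values and may be part of the cause, as Ifnb1 had 11, 3 and 5 counts in Dicer KO vehicle and 0 in each control vehicle library (adjusted p = 0.000358, edgeR), at least 7.44-fold higher. What raised Ifnb1, and whether loss of Dicer or the difference in Lyz2 goes with it, stays open.

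Reads assigned to no gene reached 46.8% of reads in the highest library (46.82%), from 45.8% in the lowest, and were used in no comparison. Counting by strand of reads that come from both strands fits, since 57 genes inside exons of an opposite-strand gene had a median count density of 1.23 times that of their partners (quartiles 0.0832 to 2.54). Of these genes 61.4% had at least 50% of the density of their partner. This does not exclude reads from introns or from between genes alone as the cause. The genes may be expressed themselves, and the test does not look at the reads on no gene. No biological explanation was tested, and reads from introns may make up part or all of the share.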

How the results depend on the processing

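Library totals and the removal of 2 libraries together were chosen after seeing the data, and all other alternatives before. Counts of genes higher and lower stayed within 1.5 times the values reported with DESeq2, limma voom, relative log expression scaling, both other filters, fits to the compared groups alone and each library left out. With DESeq2 they were 3237 and 2387 for genotype in vehicle, 4211 and 3066 in LPS, 5437 and 5377 for LPS in control, 5646 and 5374 in Dicer KO, and 2228 and 2061 for the interaction. Leaving out 1 library gave 2952 to 3802 and 2290 to 3151 for genotype in vehicle, 3623 to 4100 and 3329 to 3908 in LPS, 5124 to 5358 and 5477 to 5790 for LPS in control, 5039 to 5271 and 5709 to 6033 in Dicer KO, and 1764 to 2199 and 2269 to 2826 for the interaction. Without control vehicle replicate 3 and Dicer KO vehicle replicate 2 together they were 3612 and 3022, 4253 and 4079, 5421 and 5806, 5235 and 5983, and 2218 and 2884 in the same order. The replicate numbers did not pair the libraries, and with the replicate block the counts were 3431 and 2879, 3962 and 3713, 5258 and 5660, 5156 and 5878, and 2051 and 2585. In the check of pairing, the highest correlation, 0.518, was between control vehicle replicate 3 and Dicer KO vehicle replicate 2. Their numbers differ, so the block cannot remove what these libraries share.

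With library totals the counts moved beyond 1.5 times, to 2229 and 4577 for genotype in vehicle, 1885 and 7626 in LPS, 3066 and 8737 for LPS in control, 2637 and 9623 in Dicer KO, and 997 and 5136 for the interaction, because dropping the scaling factors shifts every gene by the same amount. The TMM factors were 1.29 to 1.31 in control vehicle, 1.19 to 1.20 in Dicer KO vehicle, 0.891 to 0.921 in control LPS and 0.707 to 0.713 in Dicer KO LPS. The same shift turned Abca1 with LPS in Dicer KO to −0.24, Dicer1 with LPS in control to −0.34 and Lyz2 with LPS in Dicer KO to −0.33. Lists not called with TMM but called with library totals, beside those named in the results, were ribosomal proteins with LPS in control (adjusted p = 0.00108) and in Dicer KO (0.00295), and with LPS in Dicer KO lysosome (0.00246), cholesterol efflux (0.0203), the tricarboxylic acid cycle (0.0476), neutrophil markers (0.041) and mast cell markers (0.0486). In the interaction they were the tricarboxylic acid cycle (0.0244), the small RNA machinery (0.0292), MHC class II (0.0292) and neutrophil markers (0.0289).

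Of 152 results of the genes with the largest changes and the genes always reported, 142 were called. Dicer1 by genotype is counted again among them as the targeted gene. Members named only through their list were not followed one by one through the alternatives. Without some library 7 lost and 2 gained the call. With the replicate block 1 lost it, and with DESeq2 1 lost it. Of 155 list tests, 47 were called, and 8 with an estimated correlation. Without some library, 8 list tests lost and 11 gained the call, and with the replicate block 2 lost it (glycolysis and microRNA host transcripts with LPS in control) and 1 gained it (MHC class II in the interaction). Gains without a library not named in the results were cholesterol efflux with LPS in Dicer KO and, in the interaction, MHC class II, nuclear-retained RNA, neutrophil markers and proliferation. Families of seed sites called in vehicle were 0 as reported, 1 with 8-base sites and 13 without control for length and GC, and in LPS they were 1 as reported, 0 with 8-base sites, 0 above 10 CPM and 16 without that control. The cause was not tested. Depth limits genes near 0 counts. Their folds in pairwise comparisons are given as bounds or with counting intervals, while their fitted differences in the interaction are no bounds. Simulated changes of 1.5-fold were recovered in 73.1% of cases for genotype in vehicle and 58.2% for the interaction.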

Other observations

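The test of the region around Dicer1 was chosen before its result was seen, and the genes named below outside the naming rule were chosen after their values were seen.

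Regulators beside the lists moved with them in some cases and not in others. Irf7, a transcription factor of the interferon response, measured 148 CPM in control vehicle, 768 in Dicer KO vehicle, 1940 in control LPS and 3460 in Dicer KO LPS. Srebf2, a transcription factor of cholesterol synthesis, rose with LPS from 80.9 to 237 CPM in control but measured 110 and 134 CPM in Dicer KO (log2 interaction −1.26, adjusted p = 0.00386). Il10, an anti-inflammatory cytokine gene, reached 45.1 CPM in control LPS and 99.8 CPM in Dicer KO LPS (log2 fold change 1.15, adjusted p = 6.06e-08). Irf3, another factor of the interferon response, differed by −0.02 in vehicle (adjusted p = 0.799) and was lower in Dicer KO LPS (−0.31, adjusted p = 0.00125). Of the interferon receptor subunits, Ifnar1 was higher in Dicer KO vehicle (0.38, adjusted p = 8.71e-06) with an interaction of −0.45 (adjusted p = 9.21e-05), and differed by −0.07 in LPS (adjusted p = 0.239). Ifnar2 differed by −0.01 and 0.07 (adjusted p = 0.881 and 0.246). Hif1a was higher in Dicer KO vehicle (0.19, adjusted p = 0.00678), where its listed targets were lower. Lyz1, the paralog of Lyz2, measured 74.1 and 71.8 CPM in control and Dicer KO vehicle, and 71.9 and 69.1 CPM in LPS. Of 17 genes of the small RNA machinery, the RNA-editing enzyme gene Adar was higher in Dicer KO (log2 fold change 1.20 in vehicle and 0.78 in LPS), as was Tnrc6a, a partner of Argonaute proteins (0.67 and 0.84), while Ago4 was lower in vehicle (−0.69) and Ago1 in LPS (−0.50).

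Single markers of other cell types differed by genotype in both directions although their lists were not called. Higher in Dicer KO were Itgax (log2 fold change 1.85 in vehicle and 1.99 in LPS) and Xcr1 (2.40 and 2.25) of dendritic cells, Itgb3 of osteoclasts (1.49 and 2.84), Kdr (2.87 and 1.03) and Cdh5 (1.92 and 1.18) of endothelium, and Hdc of mast cells (1.88 and 1.36). Kmo, another dendritic cell marker, was lower in vehicle (−1.35) and higher in LPS (1.91). Lower in Dicer KO were Il1rl1 of mast cells (−1.03) and Vwf of endothelium (−0.66) in vehicle, Ffar2 (−1.39) and Batf3 (−0.99) of dendritic cells in LPS, Cd79b of B lymphocytes in LPS (−1.05), and Ighm of B lymphocytes (−1.07 in vehicle and −0.45 in LPS). The LPS responses of both genotypes had 4496 genes called higher in both and 4886 called lower in both. Independent calls, equally likely for every gene, would give 1966 and 2428, though both responses come from the same model. Of 9633 genes called in both, 97.4% had the same direction.

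Dicer KO and control mice could also differ in the chromosome segment around Dicer1, which would place changed genes near it. Of 50 tested genes within 5 Mb of Dicer1, 4 changed at least 2-fold in vehicle (8.0%), against 6.93% elsewhere (two-sided Fisher exact p = 0.777), and in LPS 5 of 50 (10%) did, against 12.7% elsewhere (p = 0.675, same exact test). Too few genes lie in the segment for the values to decide.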
